A study of Mus musculus with 2 samples.

How the data were processed

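Chromatin from whole hearts of mice on postnatal day 0 was immunoprecipitated with an antibody against H3K27ac and sequenced, with a fragment size range of 300 to 500 bp, per the labels. The strain is B6NTac;B6NCrl/Lap. The labels give 1 group with 2 biological replicates and name the same donor entry for both; they do not say how the animals were divided between the pools beyond the 15 mice of replicate 1. Per the sample descriptions deposited with the files, the authors called intervals on mm10 in narrowPeak format 4 times: on replicate 1 with a control, on replicate 2 with a control, on both replicates and 2 controls together (the pooled list), and as a replicated list derived from the other 3. The aligner, peak caller, its version and its thresholds are not given in the sources used here. The alignments and controls were not used here.

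Each interval has a signal value, which per the file format is the authors' overall enrichment of that interval and is never negative; its scale against the control is not given in the sources used here. Significance is deposited as −log10 p and −log10 q per interval, and the position of the summit as an offset. The lowest −log10 p in the lists was 2.02, 2.01, 2.05 and 2.08 for replicate 1, replicate 2, pooled and replicated, so weak intervals were retained by the authors. A called interval depends on depth and threshold as well as on the mark: a deeper library yields more and wider intervals, and the lists show no depth. No difference in signal between lists was therefore tested. Signal values were used to describe, rank or filter intervals within a list, to correlate the replicates by rank, to order the members of a gene list by their mean over the replicates, and to test, among the additional observations, how the marked genes of a list rank within the replicated list; values of both replicates are given side by side. All intervals in each list were distinct and contained their summit. No column of any other sample was present.

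Genes and TSSs came from GENCODE release M21 and sequence from the RefSeq copy of GRCm38, the assembly that mm10 names; every interval and gene lay inside the reference chromosome lengths. The autosomes and X held 21670 protein-coding genes with a protein-coding transcript. Such genes on all assembled chromosomes, Y included, had 54361 TSSs. Of 583 distinct genes on the lists 582 were found; Ahsp was not. A further 24 genes shared a symbol with another gene and were kept under their identifiers. That rule was set after the first run had been seen, the whole analysis was then repeated, and the counts of lists above and below random were the same in both runs. A promoter was 1 kb either side of a TSS, and an interval that overlapped it by any base counted as a promoter interval. The places of the rest were exon, intron and intergenic, in that order, by whether the summit lay in an exon or the body of any annotated gene, coding or not, and the distal intervals were those outside every promoter window. Intervals on assembled chromosomes entered these steps; gene lists were drawn from the autosomes and X.

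Replicates were compared by the share of intervals with at least 1 base in the other replicate, with exact binomial (Clopper-Pearson) intervals, against 100 shuffles within chromosomes. A share of intervals is not a share of reads, and these intervals do not cover variation between animals. For each of 24 gene lists, the share of members with a promoter interval was set against 10000 random lists of equal size, and the mean number of distal intervals in the gene body and 50 kb either side against 10000 lists matched on decile of the length of that territory. Two-sided empirical p-values were adjusted over the 24 lists by Benjamini and Hochberg, with 0.05 as threshold; the smallest possible p is 0.0002. Of 24 lists, 21 had an unadjusted p under 0.05 at promoters and 12 in distal intervals. Lists overlap: of the 12 ventricular genes 9 are on another list too, as are 6 of the 30 contractile genes. Neighbouring genes such as Myh6 and Myh7 share most of their territory and Hadha and Hadhb a promoter interval, and Hox genes lie in clusters, so members are not independent. Distal intervals 12.5 kb or less apart were stitched, clusters were ranked by covered bases, and the first 500 were assigned to the nearest TSS. For 20 motifs, exact matches to a consensus on either strand were counted in the 200 bp around distal summits and in windows 2 kb to either side that touched no interval, sampled to the same bins of 5% GC, with Fisher's exact test. Replicate-specific distal intervals near list members were compared between replicates by Fisher's exact test.

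The lists, motifs, tests and most alternatives were fixed before the data were examined, as was the rule for naming genes: a set of anchor genes; per list the 3 members with the highest mean promoter signal, the 2 with most distal intervals, and members without a promoter interval (in lists of other tissues, with one) where there are 4 or fewer; the 10 clusters with most covered bases; the 10 widest promoter intervals; and the 10 intervals with the highest signal. Members that added nothing new were left out, and other members named as examples or to complete a count were chosen after their values were seen. Alternatives were a −log10 q of at least 5, a signal of at least 4, promoter windows of 500 bp and 2.5 kb, territories of 10 and 100 kb, covered bases in place of counts, random lists matched on promoter CpG content or not matched on length, other stitching distances (5 and 25 kb), cluster numbers and rankings, motif windows of 100 and 400 bp, flanks at 5 kb, other definitions of overlap, the pooled list, and each replicate alone. The replicated intervals that overlap an interval of each replicate by 50% of either length, matching on promoter mark, and leaving out germ cell genes were added after the data were seen. No sample was left out. With 1 group of 2 samples, no test between groups and no outlier test applied.

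The tests were tried on simulated data first. Of 4 planted distal lists, 2 were recovered at 1.5-fold and 4 at 3-fold; of 4 planted promoter lists, 0 were recovered where 70% of members were marked and 3 where 90% were, so moderate differences in lists of 25 genes can be missed. Of 304 unchanged lists, 1 was called in distal intervals and 0 at promoters. These lists were drawn from the same genes as the random lists, so their low call rate follows largely from the design. The simulated distal background lay at random places of the chromosomes and lacked the gathering of real intervals around genes. Planted distal lists may therefore have been easier to recover than real ones. Both planted motifs, placed in 3% of windows, were called and 0 of 18 others. These windows were random letters, without genome sequence, GC matching or flanks. The check therefore cannot show how often real sequence gives false calls. A planted share of 70% common intervals was returned as 70.0%, which the construction of this check fixed in advance. Its second list held only the common intervals, shifted by less than their width, so it tests the counting and nothing more. A first version of this simulation adjusted p-values over all simulated lists at once and recovered fewer of them; after its result was seen it was changed to 24 lists at a time, as in the analysis. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, pysam 0.24.0, samtools 1.23.1 and bedtools 2.31.1 were used.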

Results

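H3K27ac, the acetylated form of histone H3 that marks active promoters and enhancers, was mapped by ChIP-seq in whole hearts of healthy newborn mice on postnatal day 0, with males and females pooled. The study holds 1 group with 2 biological replicates. Replicate 1 was made from the hearts of 15 mice, and replicate 2 from pooled mice whose number the labels do not state. The peak lists gave the position, signal value and significance of each marked interval on the mouse genome build mm10. They carry no read numbers, so the depth of each library is unknown and the confidence intervals given cover counting error only. The design has no second tissue, age or treatment. The comparisons it allows are therefore between the replicates, between genes of different cell types within the heart, and between marked sequence and its unmarked neighbourhood.

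The mark covered a small part of the genome in both replicates, and most marked places were found in each of them. Replicate 1 had 97009 intervals over 63.3 Mb (2.32% of the assembled chromosomes) and replicate 2 had 94369 over 60.2 Mb (2.21%). The list of replicated intervals held 66471, which covered 69.8 Mb (2.56%) with a median width of 720 bp, and the list called on the replicates together held 111088 over 81.5 Mb (2.99%). Of the replicate 1 intervals on assembled chromosomes, 67.7% shared at least 1 base with an interval of replicate 2 (95% exact binomial interval 67.4 to 68.0), against a mean of 4.78% and a maximum of 4.95% in 100 shuffles. In the other direction the share was 70.9% (70.6 to 71.2), against a mean of 4.92% and a maximum of 5.13%. The bases common to the replicates came to 45.5 Mb, a Jaccard index of 0.584.

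Intervals found in a single replicate were narrower and weaker than shared ones. In replicate 1 the median width was 239 bp for the 31324 specific intervals and 534 bp for shared ones, with median signal values of 3.11 and 4.53. In replicate 2 the 27463 specific intervals had a median width of 226 bp against 508 bp, and a median signal of 3.38 against 4.84. Promoters made up 8.08% of the specific intervals of replicate 1 and 7.99% of those of replicate 2, against 24.6% and 24.3% of the shared ones. Among intervals with a −log10 q of at least 5, 90.8% in replicate 1 and 95.5% in replicate 2 touched an interval of the other replicate. Across the 54673 replicated intervals that touched an interval of each replicate, the signal values of the replicates had a Spearman correlation of 0.764; this is a correlation across intervals, which are not independent replicates. The replicated list also contained 11241 intervals that touched an interval of 1 replicate only and 551 that touched none, and how these entered it is not given in the sources used here. The shared share moved with the definition of sharing, to 43.5% in replicate 1 and 44.8% in replicate 2 where a reciprocal overlap of 50% was asked for.

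Intervals at promoters were wider and had higher signal values than those elsewhere. Of the replicated intervals on assembled chromosomes, 15320 (23.0%, 22.7 to 23.4) reached within 1 kb of the transcription start site (TSS) of a protein-coding gene, 6.15 times the 3.75% of shuffled intervals. Their median width was 1083 bp and their median signal 9.58, against 651 bp and 4.41 for intergenic intervals. Any overlap with the window made a promoter interval, whereas the other places went by the summit. Wide intervals therefore enter the promoter class more readily, and the difference in width is set in part by this rule. Introns held most of the rest, 49.3% of intervals (1.22 times the shuffled share), exons held 5.84% (1.41 times), and intergenic sequence held 21.8% where 51.8% was found after shuffling. By gene, 11826 of 21670 protein-coding genes (54.6%) had a replicated interval at a promoter. Replicate 1 alone marked 12058 genes and replicate 2 alone 11995, and 11556 genes were marked in each.

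Genes of the cardiomyocyte contractile apparatus were marked without exception: all 30 of the 30 genes on that list had a promoter interval in the replicated list and in each replicate, where random lists of the same size had a mean of 54.5% and a 95% range of 36.7 to 73.3%. The genes of the cardiac myosin heavy chains lay above the 90th percentile of marked genes in each replicate. Myh6, the alpha heavy chain (chromosome 14, 54941921 to 54966927), had a highest promoter signal of 26.2 in replicate 1 and 42.9 in replicate 2, and Myh7, the beta heavy chain (chromosome 14, 54970684 to 54994626), had 25.5 and 31.8. Over all marked genes the median was 10.8 in replicate 1 and 12.8 in replicate 2, and the 90th percentile was 25.4 and 30.9. The highest mean of the list belonged to Myom1, a protein of the sarcomere M-band, at 46.9 and 69.9, followed by Ldb3, a Z-disc protein, at 41.4 and 41.9, and the chaperone gene Cryab at 30.8 and 41.8. Cardiac troponin T (Tnnt2, 26.1 and 40.5), troponin I (Tnni3, 21.2 and 38.1), the fetal slow troponin I gene Tnni1 (21.5 and 23.7), cardiac actin (Actc1, 21.8 and 25.4), the giant filament protein titin (Ttn, 23.1 and 30.2) and the ventricular light chain Myl2 (33.1 and 29.1) also lay above the median of marked genes in each replicate. The atrial light chain Myl7 was lower, at 4.80 and 5.79. Signal values are the authors' own per interval. Apart from the order of members by their mean over the replicates, they are set here against other intervals of the same replicate only. That order did not hold within each replicate: in replicate 2 Myh6 (42.9) stood above Ldb3 (41.9).

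Cardiac transcription factors were marked in 28 of 30 cases. Gata4 (chromosome 14, 63198922 to 63271692) had signals of 35.2 and 42.7, Mef2a 32.6 and 54.5, Meis1 30.2 and 46.9, Mef2c 33.2 and 32.0, Hand2 28.4 and 20.6, Tbx20 19.2 and 26.5, Nkx2-5 14.9 and 25.9, and Tbx5 16.4 and 10.5. The members without a replicated promoter interval were Gata5 and Isl1, the latter a factor of early cardiac progenitors. Of the calcium handling and ion channel genes 22 of 26 were marked, among them the sarcoplasmic reticulum calcium pump Atp2a2 (26.7 and 50.5), the ryanodine receptor Ryr2 (26.7 and 32.2), the sodium-calcium exchanger Slc8a1 (25.6 and 42.9), phospholamban (Pln, 20.0 and 23.8), connexin 43 (Gja1, 19 and 26.8) and the potassium channel Kcnq1 (19 and 21.9). Kcnd3, Hcn2, Sln and Fkbp1b were not marked. All 12 ventricular genes were marked, and of the natriuretic peptide and atrial genes 13 of 16, without Sln, Bmp10 and Stard10. Nppa, the atrial natriuretic peptide gene, had a low promoter signal of 5.16 and 5.45, and its neighbour Nppb, the brain natriuretic peptide gene, had 17.0 and 16.3.

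Genes of energy metabolism and growth were marked to a similar extent. The list of fatty acid oxidation had 26 of 27 genes marked, with Acadl, the long-chain acyl-CoA dehydrogenase, at 51.8 and 58.8 and Cpt1b, the muscle carnitine palmitoyltransferase, at 33.6 and 46.0; the exception was Plin5. The mitochondrial respiratory chain had 29 of 29 marked (Cox5a, a subunit of cytochrome oxidase, 44.4 and 47.3), glycolysis 21 of 21 (the muscle enolase Eno3, 30.6 and 34.1), cytosolic ribosomal proteins 30 of 30 (Rpl7, 39.1 and 30.8), the cell cycle 29 of 30 without Bub1, and immediate early and stress genes 22 of 24 without Fosl1 and Egr3 (the messenger RNA decay factor gene Zfp36, 45.1 and 41.3; Jun, 29.3 and 46.1).

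Endothelial, fibroblast and smooth muscle genes were mostly marked as well. Endothelial and endocardial genes were marked in 29 of 30 cases, all except Plvap, with the endothelial adhesion molecule Pecam1 at 15.7 and 17.3. Fibroblast and matrix genes were marked in 26 of 28, with Tcf4, a widely expressed helix-loop-helix factor, at 40.7 and 39.9. The exceptions were Thy1 and Postn; the latter had an interval in replicate 2 only (3.81). Smooth muscle and pericyte genes were marked in 16 of 20, with the smooth muscle actin Acta2 at 15.6 and 16.2 and without Lmod1, Rgs5, Itga8 and Vtn. Epicardial genes were marked in only 5 of 16 (31.3%, random mean 54.3%), including the factor Wt1 at 5.52 and 6.60, and macrophage and other leukocyte genes in 9 of 24 (37.5%, random mean 54.6%). Neither list passed the test. Ptprc, the pan-leukocyte surface protein CD45, and likewise Tyrobp, Cd3e, Laptm5 and Coro1a had a promoter interval in replicate 1 and none in replicate 2.

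Genes of other tissues were mostly unmarked, as was the list of Schwann cells, neurons and neural crest within the heart. The list of hepatocyte genes had 2 of 30 marked (Trf and Foxa3), neurons of the central nervous system 1 of 30 (Camk2a, 22.7 and 19.9), lung, gut and pancreas epithelium 4 of 29 (Vil1, Cpa1, Trp63 and Elf3), germ cells and pluripotency 2 of 26 (Dazl and Tex14), Hox clusters 6 of 32, and the Schwann and neural crest list of the heart 2 of 17. The last pair were Hand2, which is on the cardiac factor list as well, and Mpz, whose promoter interval also covers the promoter of the respiratory chain gene Sdhc. Albumin (Alb), the neuronal factor Neurod1, the muscle determination factor Myod1, the erythroid enzyme Alas2 and the lung surfactant gene Sftpc had no promoter interval in either replicate. Of skeletal muscle genes 9 of 29 were marked, led by the muscle creatine kinase Ckm at 24.9 and 15.2, and of erythroid genes 5 of 19, namely Tfrc, Sptb, Nfe2, Tal1 and Bpgm. The globin genes on that list were unmarked, and since Hba-a1 and Hba-a2, like Hspa1a and Hspa1b among the stress genes, are near-identical copies, their calls are uncertain.

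Each of these 24 lists was set against 10000 random lists of equal size drawn from protein-coding genes, with a two-sided empirical p adjusted over the lists by Benjamini and Hochberg. Above random were 13 lists. The contractile, cardiac factor, fatty acid oxidation, respiratory chain, glycolysis, cell cycle, endothelial, fibroblast and ribosomal lists had a permutation p of 0.0002, the smallest that 10000 lists can give (adjusted 0.000343), and the immediate early (0.00064), ventricular (0.0012), calcium and channel (0.00453) and smooth muscle (0.0411) lists followed. Below random were 8 lists: hepatocyte, central neuron, epithelial, germ cell and Hox lists (0.000343 each), Schwann and neural crest (0.00169), erythroid (0.0221) and skeletal muscle (0.0221). The natriuretic and atrial (0.0558), epicardial (0.114) and leukocyte (0.140) lists did not pass. Genes are not replicates, so these p-values describe the 2 libraries. The 32 Hox genes lie in clusters, and keeping 1 member per 500 kb would leave 4 of them. Random lists of 32 separate genes are therefore not a like comparison, and the Hox p is descriptive only. That thinning was run for distal intervals and not at promoters. The smooth muscle call was lost in 6 of 9 alternative settings (adjusted p 0.0590 to 0.291), the erythroid call without replicate 2 (0.0635) and in the pooled list (0.112), and the skeletal muscle call without replicate 1 (0.0922), while other lists passed in some settings: leukocyte genes as below random in 4, among them without replicate 1 (5 of 24 marked, 0.00192), epicardial genes as below random in 2 (0.0436 and 0.0190), and natriuretic and atrial genes as above random in 6, among them without replicate 2 (15 of 16 marked, 0.00293). With random lists matched on promoter CpG content, the erythroid (0.576), skeletal muscle (0.351) and immediate early (0.104) lists no longer passed and the natriuretic and atrial list did (0.0119).

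**Figure D1:**
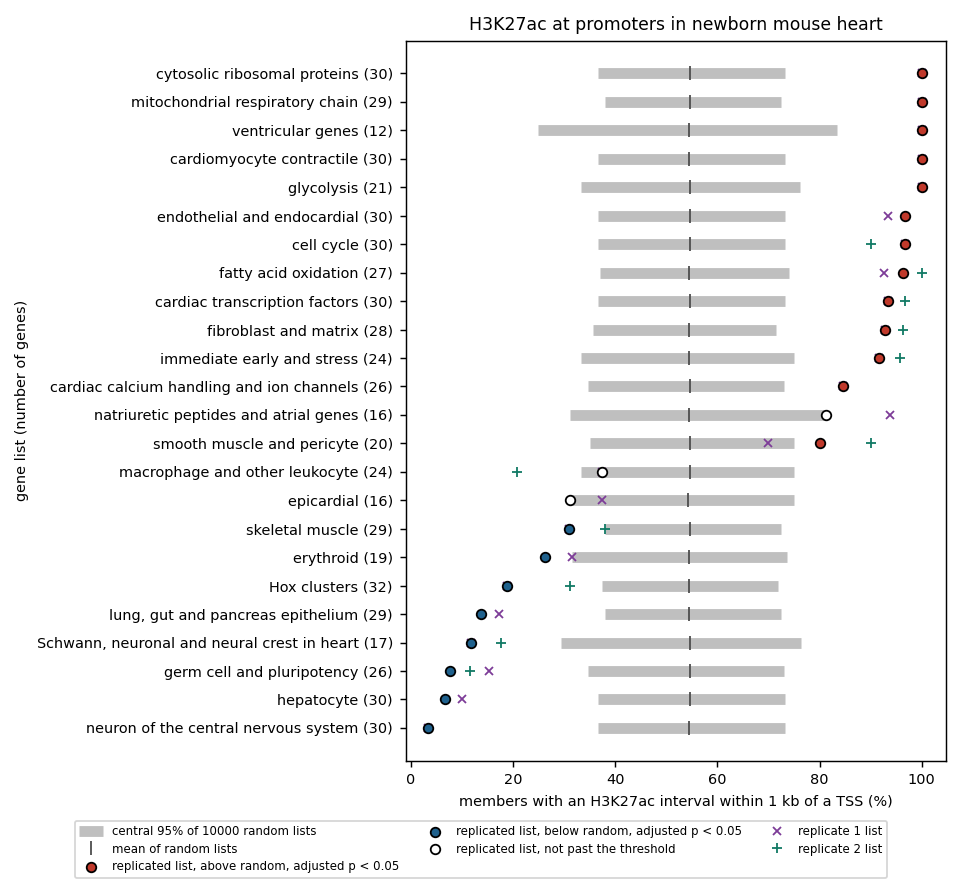
Share of the genes on each of 24 lists that had an H3K27ac interval within 1 kb of a TSS (horizontal axis, percent; the number of genes on the list in brackets). Circles give the replicated list, red above and blue below random lists at adjusted p under 0.05 and white otherwise; crosses and plus signs give replicates 1 and 2 and are hidden behind the circle where they coincide with it. Grey bars span the central 95% of 10000 random lists, with their mean as a line. The 30 contractile genes stand at 100% and the 30 genes of central neurons at 3.33%.

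Intervals outside all promoter windows, called distal here, gathered around heart genes. Calcium handling and ion channel genes had a mean of 22.5 distal replicated intervals in the gene body and 50 kb either side, 3.27 times the 6.86 of random lists matched on the length of that territory. The exchanger Slc8a1 (chromosome 17, 81373105 to 81738377) had 97, the calcium channel subunit Cacna1c 79 and Ryr2 56. On replicates 1 and 2 alone these genes had 169 and 156, 134 and 138, and 107 and 90. The list mean there was 36.3 and 34.8 against random means of 10.6 and 10.3. Cardiac transcription factors had a mean of 14.9 (2.91 times random), with 41 at Myocd, a coactivator of smooth and cardiac muscle genes, and 33 at Gata4. Contractile genes had 14.2 (2.94 times), with 37 at Ttn and 35 at the sarcomeric actinin Actn2, and ventricular genes 11.8 (3.51 times), with 47 at Fhl2. On replicates 1 and 2 alone Myocd had 56 and 68, Gata4 60 and 58, Ttn 60 and 74, Actn2 48 and 62, and Fhl2 70 and 73.

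Distal intervals also stood above random around genes of other heart cell types and of general functions. Endothelial genes had a mean of 13 (2.48 times random), with 48 at the transcription factor Ets1 and 33 at the growth factor receptor Kdr; smooth muscle genes 10.2 (2.00 times), with 45 at Synpo2; fibroblast genes 9.86 (1.89 times), with 60 at Tcf4; fatty acid oxidation genes 9.41 (2.03 times); immediate early genes 8.17 (3 times), with 33 at Dusp1; and ribosomal protein genes 6.13 (2.45 times). Lower than random were genes of central neurons, with a mean of 1.67 against 4.36, and Hox genes, with 1.34 against 2.66. Over all genes the mean was 4.31, the median 2 and the 95th percentile 15. The means of the 10 lists above random exceeded their medians, which were 14.5 for calcium and channel genes, 13.5 for cardiac factors, 11.5 for contractile, 10 for endothelial, 8.5 for ventricular and for smooth muscle, 7 for immediate early, 6 for fatty acid, 5.5 for fibroblast and 5 for ribosomal protein genes. Natriuretic and atrial genes had 8.31, with 39 at Pam, glycolysis genes 5.95, cell cycle genes 5.10, Schwann and neural crest genes 4.24, epicardial genes 3.69, skeletal muscle genes 3.62, germ cell genes 3.38, respiratory chain genes 3.10, leukocyte genes 3.04, erythroid genes 2.84, epithelial genes 2.62 and hepatocyte genes 2.20; none of these 12 lists passed.

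The same kind of test, with two-sided empirical p and adjustment over 24 lists, gave 10 lists above and 2 below random. The calcium, cardiac factor, ventricular, immediate early and ribosomal lists lay at the smallest p of 0.0002 (adjusted p 0.00096), followed by the contractile (0.0032), central neuron (0.00549), fatty acid (0.0102), endothelial (0.0117), fibroblast (0.0259), smooth muscle (0.0423) and Hox lists (0.0440), and the nearest list that did not pass was the natriuretic and atrial one (0.124). Where random genes were also matched on whether their promoter was marked, the fatty acid (0.0555), smooth muscle (0.0648), fibroblast (0.106), Hox (0.331) and central neuron (0.684) lists no longer passed and the Schwann and neural crest list did, above random (0.0450); without matching on length the ribosomal list did not pass (0.225). The smooth muscle call also ended in 5 other settings (0.0532 to 0.199), still at 1.69 times random without intervals within 5 kb of any TSS, 1.75 with matching on marked promoters nearby and 1.72 with matching on the promoter mark, the central neuron call with matching on marked promoters nearby (0.474 times random, 0.0756), and the Hox call in most settings, including on either replicate alone (0.290 on replicate 2, 0.0775 on replicate 1), though not without intervals within 5 kb of any TSS (2 intervals, 0.0560 times random, 0.00096) or with matching on marked promoters nearby (0.485 times, 0.0211), while hepatocyte genes passed as below random with 10 kb either side (0.0288) and in the pooled list (0.0280).

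**Figure D2:**
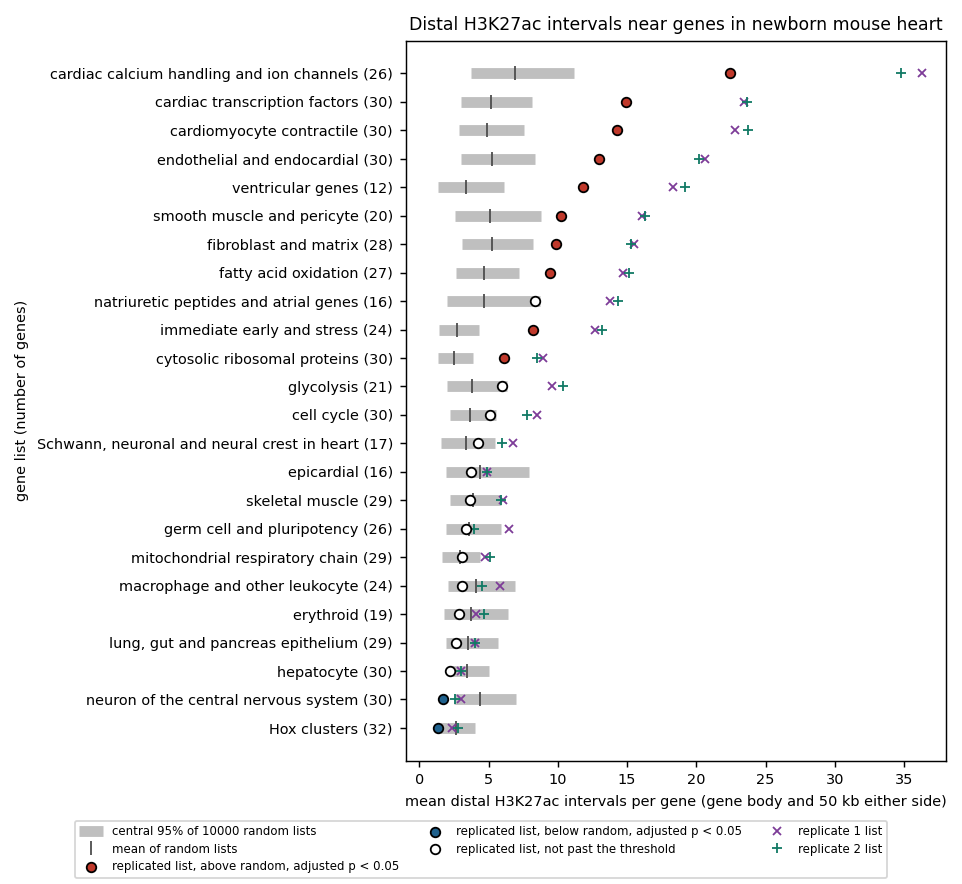
Mean number of distal H3K27ac intervals per gene, counted in the gene body and 50 kb either side (horizontal axis), for 24 gene lists (number of genes in brackets). Circles give the replicated list, red above and blue below random at adjusted p under 0.05 and white otherwise; crosses and plus signs give replicates 1 and 2, whose lists hold more and narrower intervals than the replicated list. Grey bars span the central 95% of 10000 random lists matched on territory length, with their mean as a line. Calcium handling and ion channel genes reach 22.5, against a random mean of 6.86.

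Stitched into clusters where they lay close together, the 51145 distal intervals formed 18376 clusters, 8648 of them single intervals. The 500 clusters with most covered bases held 23.9% of all bases in distal intervals, covered at least 13.4 kb each and had a median of 16 intervals. Of these, 24 had as their nearest TSS that of 1 of the 86 genes on the contractile, cardiac factor and calcium and channel lists, among them Gata4, Nkx2-5, Tbx20, Mef2c, Meis1, Ryr2, Atp2a2, Slc8a1 and Pln. Matched random gene sets had a mean of 3.14 and a 95% range of 0 to 7, a 7.64-fold difference (permutation p = 0.0002, the smallest possible with 10000 sets). These sets were matched on territory length alone, not on promoter mark or on the distance to neighbouring genes. Assignment to the nearest TSS can favour genes with few neighbours, and its part in the difference was not tested. Territories of cardiac factors held a mean of 0.3 marked promoters of other genes, against 1.12 for calcium and channel genes and 1.93 for contractile genes. Cardiac factors accounted for 13 of the clusters, calcium and channel genes for 9 and contractile genes for 2. Endothelial genes were nearest to 7, among them Kdr, Pecam1 and Notch1.

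None of the 10 clusters with most covered bases had as its nearest gene a member of those 3 cardiomyocyte lists. The first lay over Rbpms, an RNA-binding protein gene (chromosome 8, 33772938 to 33924470), with 60 intervals covering 107.9 kb. Next came Rbm20, a splicing factor of titin (99.8 kb), Msi2 (99.2 kb), the collagen pair Col4a1 and Col4a2 (79.5 kb), Tns1 (72.9 kb), Nfia (65 kb), Igf2r (63.6 kb), the ventricular list gene Fhl2 (63.4 kb), Lrrfip1 (63.0 kb) and Nfib (60.3 kb). Each of the 10 overlapped the body of the gene it is named for.

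Of the 10 widest intervals over promoters, 6 lay at genes of the contractile and cardiac factor lists. The first was at Myh7 (chromosome 14, 54981716 to 54999384), 17669 bp wide, and the third at Myh6 (54957081 to 54973854), 16774 bp wide, which also reached into the 3′ part of Myh7 and over the antisense gene Mhrt. Between them was Atp1a1, the sodium pump subunit (17167 bp), and after them came Tnnt2 (15803 bp), Actn4 (15445 bp), Mef2d (15279 bp), the neighbours Dapk3 and Nmrk2 (14407 bp), Hand2 (14339 bp), Gata4 (13900 bp) and Bcl9l (13595 bp). By signal value instead of width the order was different: the 10 highest replicated intervals, with pooled signals from 65.2 to 73.5, lay at the promoters of Syde2, Zc3h4, Nr2c2, Actb, Cdk12, Creb1, Zfp827 and Acadl and at 2 noncoding loci, 1810026B05Rik and D630033A02Rik with Mirlet7i. Since distal was defined by protein-coding TSSs, the promoters of noncoding genes such as these counted as distal.

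**Figure D3:**
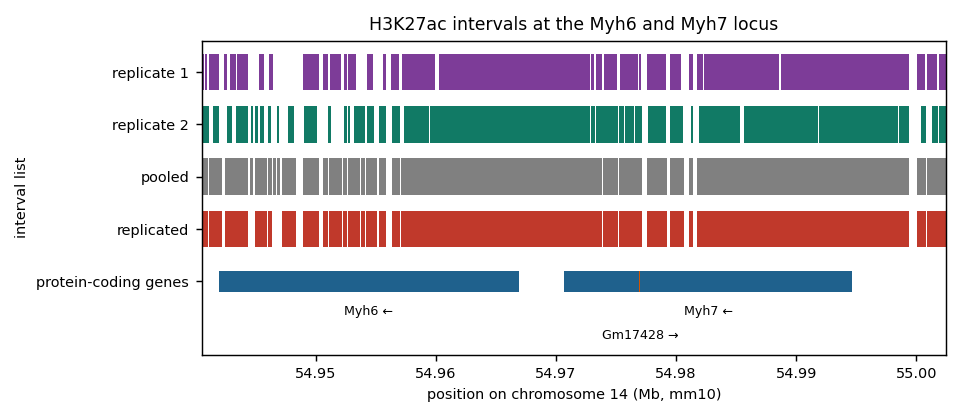
H3K27ac intervals along chromosome 14 at the Myh6 and Myh7 genes (horizontal axis, position in Mb on mm10), drawn to scale for replicate 1, replicate 2, the pooled list and the replicated list, with the bodies of protein-coding genes below and arrows for their direction. Continuous blocks cover the promoter ends of Myh6 (16774 bp) and Myh7 (17669 bp) in the replicated list, and the replicates break them into at most 4 intervals each.

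Distal intervals were richer than the sequence beside them in matches to several binding motifs, among them those of factors that act in heart muscle. Of 20 motifs, 6 were enriched in the 200 bp around the summits of 43670 distal intervals over GC-matched windows 2 kb away. MEF2, the site of the myocyte enhancer factors, had the highest odds ratio, 2.40 (95% interval 1.87 to 3.08, 0.483% of windows against 0.202%, Fisher's exact test, adjusted p = 5.01e-12). A CAGCTG E-box entered as the proneural type, a core that muscle and other helix-loop-helix factors bind as well, followed at 1.43 (1.36 to 1.5, 9.55% against 6.87%, adjusted exact p = 8.4e-46). GATA sites had 1.30 (1.19 to 1.41), FOX sites 1.29 (1.18 to 1.40), sites of the ERR nuclear receptors, regulators of mitochondrial genes, 1.27 (1.08 to 1.5, adjusted exact p = 0.00896) and SOX sites 1.22 (1.11 to 1.33).

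A further 4 motifs passed the adjusted p with odds ratios above 1 but below the set minimum of 1.2: MEIS (1.19), TEAD (1.15), NKX2-5 (1.13) and RUNX (1.12). The CTCF core was rarer at summits than beside them (0.272), as were the TBX (0.815) and HAND (0.883) motifs. These ratios cover only the 200 bp around the summit, so they do not show whether such sites are rarer over whole intervals. ETS, HNF4, AP-1 (1.01), the CArG box of SRF (0.917), the POU octamer (0.886), NRF1 and HNF1, which had 1 match in all, did not pass. Fisher's exact test over windows was two-sided with adjustment over 20 motifs; windows are not replicates, and exact consensus matching misses weaker sites. ERR was not enriched with windows of 100 bp (odds ratio 1.12, adjusted p 0.449) or flanks at 5 kb (1.19, 0.0511), GATA fell just below the minimum of 1.2 on replicate 2 alone, SOX did so with flanks at 5 kb (1.19) and on replicate 1 alone (1.13), and the MEF2 odds ratio rose to 4.07 with windows of 400 bp.

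**Figure D4:**
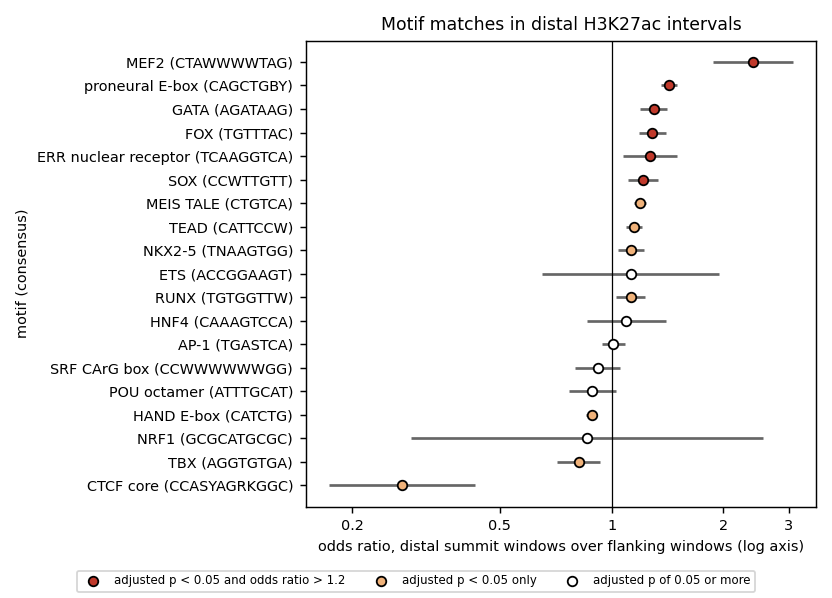
Odds ratio (horizontal axis, log scale) for a motif match in the 200 bp at the summits of distal H3K27ac intervals over GC-matched windows 2 kb away, with 95% intervals as lines. Red marks adjusted p under 0.05 with an odds ratio over 1.2, orange adjusted p under 0.05 alone, and white neither; HNF1, with a match in 1 window, is not drawn. MEF2 stands highest at 2.40 and the CTCF core lowest at 0.272.

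The replicates were also compared by the share of distal intervals near list members that were found in 1 replicate alone. Such a share also depends on depth and threshold, so it cannot tell whether a replicate held more of another tissue. For 23 of 24 lists, the share of specific intervals near members did not pass a test of difference between the replicates. Around contractile genes it was 28.1% in replicate 1 and 27.8% in replicate 2, around cardiac factors 34.2% and 29.3%, around endothelial genes 31.3% and 29.1%, and around leukocyte genes 44.6% and 32.4% (Fisher's exact test, adjusted p = 0.483). Germ cell and pluripotency genes were the exception: 69 of 138 distal intervals (50%) were specific in replicate 1 and 24 of 96 (25%) in replicate 2 (odds ratio 3, two-sided Fisher's exact test, p = 0.000136, adjusted p = 0.00325 over 24 lists). The test compares 2 libraries of 1 group, not conditions. Places shared by the replicates enter on both sides of it, and neighbouring intervals are not independent, so its p-values are descriptive only. Without the neighbours Prm1, Prm2 and Tnp2, which share a locus, the shares were 45.4% and 25.3%. The germ cell call was then lost (adjusted exact p = 0.0894). It was also lost with a −log10 q of at least 5, where the contractile list passed instead. The germ cell shares there were 41.4% and 19.5% (odds ratio 2.91, from 58 and 41 intervals, adjusted exact p = 0.175). With a signal of at least 4 the call was lost too (odds ratio 1.31, adjusted exact p = 0.697). The 4 lists that passed in that setting were the calcium and channel, ventricular, smooth muscle and epithelial lists.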

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

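The weighing of technical explanations in this part used tests that were chosen after the main results were seen. Intervals outside the chromosomes from which gene lists were drawn were looked at because no gene list test uses them: 4 replicated intervals lay on the Y chromosome and 6 on unplaced scaffolds. The hearts were pooled from males and females, and nothing further was tested on them.

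The first pattern is the excess of distal intervals around contractile, cardiac factor, and calcium and channel genes. If every gene with a marked promoter had as many, matching random genes on the promoter mark would remove it; the 3 lists stayed above random, 2.18 to 2.63 times (highest adjusted p 0.0202). Leaving out intervals within 5 kb of any annotated TSS, noncoding ones included, left folds of 2.62 to 3.54 (highest adjusted p 0.0151), and keeping 1 member per 500 kb left folds of 2.86 to 3.27 (0.0048). These tests argue against marked promoters as such, misassigned promoters or double counting of neighbours as the whole cause. The matching used only the presence of a promoter interval, not its width or signal. Marked contractile, cardiac factor and calcium genes ranked high among marked genes, with mean width percentiles of 88.3, 89.2 and 85.9. Their mean signal percentiles were 78.0, 72.2 and 67.7. Whether such wide or strong marking adds to the excess was not tested. Another hypothesis that remains is that heart muscle genes have more active distal elements in the newborn heart. Staying above random was not particular to heart muscle genes. The immediate early, endothelial and ribosomal lists also did so in each of these tests. With matching on the promoter mark they stood at 1.99, 1.83 and 1.46 times random. With 1 group, no biological explanation was tested, and the lists were counted on the same 2 libraries throughout.

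The second pattern is the excess around cytosolic ribosomal protein genes. It remained at 2.5 times random without intervals near any TSS (adjusted p 0.0048) and at 1.74 times with random genes matched on the number of other marked promoters nearby (0.0030), which argues against those explanations as the whole cause. Matching on the gene's own promoter mark lowered the ratio from 2.45 to 1.46 (adjusted p 0.0450, random 95% range 2.93 to 5.67 against the observed 6.13), and this test lay on the other side of the threshold in the run made before genes with a shared symbol were kept. A general excess of distal intervals at genes with marked promoters therefore cannot be told apart from one of ribosomal protein genes: the random mean rose from 2.51 to 4.21 with the matching and the remaining excess sits at the threshold. No biological explanation was tested.

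The third pattern is the enrichment of MEF2 and CAGCTG motifs at distal summits, where base composition beyond GC content could give the same result. None of 100 rearrangements of the MEF2 letters reached its odds ratio of 2.40; the highest was 1.41 and the median 0.988, which argues against composition as the cause for MEF2. For the CAGCTG box 2 of 100 rearrangements were as high as 1.43, the highest at 1.49 and the median at 1.10, and 49 contained a CG that the box itself lacks, so composition stays open there. A hypothesis for MEF2 is that its sites mark active heart elements, which these data alone cannot separate from other sequence features near them; no biological explanation was tested.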

How the results depend on the processing

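The tests on the list restricted to intervals found in each replicate, on random genes matched on promoter mark and on leaving out germ cell genes were chosen after the results were seen. No result past its threshold changed direction. At a signal of at least 4 the replicated list held 42050 intervals, and 44433 to 54993 under the other definitions. The share of replicate 1 intervals found in replicate 2 was 75.4% and 78.3% with a −log10 q of at least 5 or a signal of at least 4 in both lists, 58.2% with 50% of the interval covered and 43.5% with reciprocal overlap of 50%; for replicate 2 these were 82.6%, 70.1%, 61.8% and 44.8%. The promoter share was 26.7% and 31.0% at the stricter q and signal, 21.5% and 27.9% with windows of 500 bp and 2.5 kb, 16.8% in the pooled list, 26.2% in intervals found in each replicate, and 19.3 to 19.6% leaving out a replicate. The number of lists whose replicate-specific share differed was 4 at a signal of at least 4 and 0 without the germ cell members of 1 locus. Without Prm1 alone the germ cell call held (Fisher's exact test, adjusted p 0.00521). That step could change little, since Prm2 and Tnp2 of the same locus stayed on the list. In replicate 1 it left 68 of 137 intervals specific, against 69 of 138 before. For shares that moved, the cause was not tested beyond the change in the intervals or windows counted.

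Other counts stayed within 1.5 times: 12 to 14 lists above random at promoters, 8 to 10 in distal intervals and 5 to 9 enriched motifs. Clusters nearest cardiomyocyte genes numbered 19 to 30 of the first 500, each at the smallest p of 0.0002, as did 14 of the first 200 and 43 of the first 1000. Of 216 list tests at promoters 192 kept their side of the threshold, 12 lost it and 12 gained it; of 264 in distal intervals the numbers were 245, 16 and 3, and of 133 motif tests 120, 5 and 8, counted by adjusted p alone and not by the minimum odds ratio. The number of distal intervals at anchor genes moved in 122 of 192 cases over the settings tried. No paired analysis was possible because there is 1 group. No list repeats an interval, so that alternative for motifs gave no value. Depth is unknown, so an unmarked promoter means no called interval and not the absence of the mark.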

Other observations

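All tests in this part were chosen after the data were seen. Among genes with a marked promoter, heart muscle genes differed from others by the width of their promoter intervals. Mean width percentiles among the 11826 marked genes were 89.2 for cardiac factors, 88.3 for contractile genes, 88.3 for ventricular genes and 85.9 for calcium and channel genes, against random 95% ranges such as 39.8 to 60.2 for contractile genes (permutation test against 10000 random lists, adjusted p = 0.00056 each over 28 tests, at the smallest possible p of 0.0002). The median width was 5462 bp for contractile and 4011 bp for cardiac factor genes, and 1335 bp for cell cycle genes, whose percentile of 46.6 did not pass (0.577). Glycolysis (80.0), fatty acid oxidation (77.7), endothelial (75.9), immediate early (72.2) and natriuretic and atrial genes (70.7) were also wider than random. Of 14 lists 9 passed above random and 0 below, and with random genes matched on number of TSSs, a matching added after the first result, the counts were 9 and 0 again. Lists with at most 9 marked members were not tested. These were the epicardial, Schwann and neural crest, leukocyte, erythroid, skeletal muscle, hepatocyte, central neuron, epithelial, germ cell and Hox lists, so no list of another tissue was among the 14.

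Width and signal did not always go together. Endothelial genes had wide intervals with a mean signal percentile of 40.8 that did not pass (permutation test, adjusted p = 0.125), and respiratory chain genes had a signal percentile of 70.2 (0.00215) with a width percentile of 59.4 that did not (0.109). Fibroblast and matrix genes had the only signal below random among the lists tested, at a mean percentile of 29.7 (0.0014; 0.000861 with matching). Signal was above random for 8 lists, and for 9 with matching, which added ventricular genes (0.0525 without and 0.0386 with it). The test does not separate a cell type's share of the tissue from the mark per cell, and no explanation was tested.

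Of the pooled intervals 44616 were not in the replicated list. They had a median width of 232 bp and a median signal of 2.74, and 7.49% lay at promoters. Of the replicated intervals 54409 overlapped an interval of each replicate by 50% of either length, with a median signal of 5.39, and the other 12056 had a median of 3.32.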
